A study of Sus scrofa with 4 samples.

How the data were processed

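Fibroblasts were grown from biopsies of shallow and deep skin wounds on the backs of 2 Duroc pigs, taken 20 weeks after wounding, and total RNA from confluent cultures was hybridized to a porcine Affymetrix expression array. There were 4 arrays, 2 from shallow and 2 from deep wounds. The 4 samples were numbered as listed, and the titles name each sample's partner by that number. The numbering itself is not stated, so the assignment of a shallow and a deep array to the same pig rests on this reading.

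The deposited values are MAS5 signal intensities on a linear scale, 1 value per probeset and array, made with MAS5 and GCOS 1.0 per the submitters' processing notes. In the table deposited by the authors, the mean of each array without the top and bottom 2% of probesets was the same, 250.1 intensity units on each array, so each array had been scaled to a common level. Scan settings and the scaling target were not given in the sources used here. The table held no detection calls, so signals were set beside those of 23 control probesets for transcripts that should be absent. Where a named gene past the threshold lay below the highest of these on an array, its fold is given as a bound, with that control's signal in place of the gene's. An array carries no read depth, and the number of arrays limits the precision.

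The 124 control probesets were left out of the tests, which left 23999. Signals under 1 were set to 1, which touched 2547 of 95996 values, and all were taken to log2. Probesets with a mean log2 signal at or above the 40th percentile, a signal of 27.1, were kept, which left 14399. Genes were named through the platform annotation. It gave 1 symbol to 10069 probesets, several to 198 and none to 13732, which are unnamed here. Gene identifiers of 9961 probesets were found in the current gene table, and no symbol needed updating. A gene was represented by its probeset with the highest mean log2 signal, and 5272 genes were measured past the filter.

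Deep and shallow arrays were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with a mean-variance trend and the pig as a block, and p-values were adjusted by the Benjamini-Hochberg method over the 14399 probesets. The block leaves 1 residual degree of freedom per probeset, to which the moderation added 6.88. Differences are deep minus shallow, with the standard error of the moderated fit. The pig was used as a block because the series describes shallow and deep wounds on the same animals. In the data, deviations of same-pig arrays from their depth means had a correlation of -0.01 across probesets. The pairing therefore comes from the design and leaves no visible mark on the values.

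The tests, the alternatives, 25 gene lists and the rule for naming genes were chosen before the data were examined. The rule took the 12 genes with the largest rise and the 12 with the largest fall among those past an adjusted p of 0.05. Where fewer passed, places were filled by the smallest unadjusted p among genes with at least a 2-fold mean difference and the same sign in both pigs, given as values only. It also took up to 4 members of each list with the largest absolute difference. Here 4 were taken from lists past the threshold and 2 from the others. ACTA2, COL1A1, COL1A2, COL3A1, TGFB1, CTGF, DCN, FN1, MMP1 and TIMP1 were added where measured; COL1A1 and CTGF had no named probeset here.

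Gene lists were tested with camera of limma at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 25 lists. Camera with an estimated correlation and fry, a rotation test of each list on its own, were run beside it. The estimated correlation rests on 1 residual per gene, because the fit has 1 residual degree of freedom. For collagens the estimate was -0.053, below the preset 0.01, yet camera's unadjusted p rose from 2.1e-07 to 0.112. A list that fails with the estimate is therefore not shown to lack a shift, and the preset correlation stays an assumption. For the lists the text gives how many members passed over all probesets or when adjusted over the list alone. For the cell-cycle list it also gives how many were at least 1.5-fold different in the same direction in both pigs. The number with both deep arrays above, or below, both shallow arrays, where given, stands against a chance share of 16.7% each way.

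The fit was tested on simulated arrays with the real means and 200 of 14399 probesets changed. It recovered 1.79% of 56 probesets changed 2-fold, 70.0% of 70 changed 4-fold and 91.9% of 74 changed 8-fold, and 8 of its 126 calls were false. With no change simulated it called 0 probesets, 716 had an unadjusted p under 0.05, and 72 were at least 2-fold higher and 56 at least 2-fold lower in both pigs. The noise was drawn independently for each probeset from the fit's own variance prior, without the quality differences between the real arrays. These rates therefore hold under the model's own assumptions and give no error rate for the real arrays.

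Alternatives were no block, the crossed pairing, quantile normalization, median centring, no filter or a stricter filter at the 60th percentile, and an offset of 9.38 before log2. Others were a variance prior without trend or with robust estimation, the mean of a gene's probesets, and leaving out each array or each pig. A fit with each array's actin 3' to 5' ratio as covariate, and 2-fold counts without a pig or an array, were added after the data were seen. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.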

Results

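Gene expression was measured in dermal fibroblasts cultured from shallow and deep wounds of 2 Duroc pigs, 20 weeks after wounding, a pig model of cutaneous fibrosis. Each pig gave 1 shallow and 1 deep array, called here the arrays of pig 1 and pig 2. Signals are in MAS5 intensity units, and group values are means ± SD over n = 2 arrays. The comparison asks how fibroblasts from deep wounds differ from those of shallow wounds in the same animal.

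The arrays had equal trimmed means but differed in their control probesets. The 28S ribosomal RNA signal was 1350 and 1830 on the shallow arrays of pig 1 and pig 2, and 3388 and 7467 on the deep arrays. Hybridization controls, added in a fixed amount, read 1326 and 1535 on the shallow arrays and 1815 and 4396 on the deep arrays. The ratio of actin signal at the 3' end to that at the 5' end, a measure of RNA integrity and labelling, was 1.96 and 2.41 for shallow and 3.28 and 6.10 for deep. Genes of epithelial cells read high on the shallow array of pig 1 alone. The adhesion gene CDH1 had a signal of 1084 there and 10.7, 17.7 and 7.15 on the shallow array of pig 2 and the deep arrays of pig 1 and pig 2. EPCAM had 979 against 4.79, 27.3 and 10.1. The closest arrays were the shallow array of pig 2 and the deep array of pig 1, with a Pearson correlation across probesets of 0.964. The farthest were the shallow array of pig 1 and the deep array of pig 2, at 0.877.

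**Figure D1:**
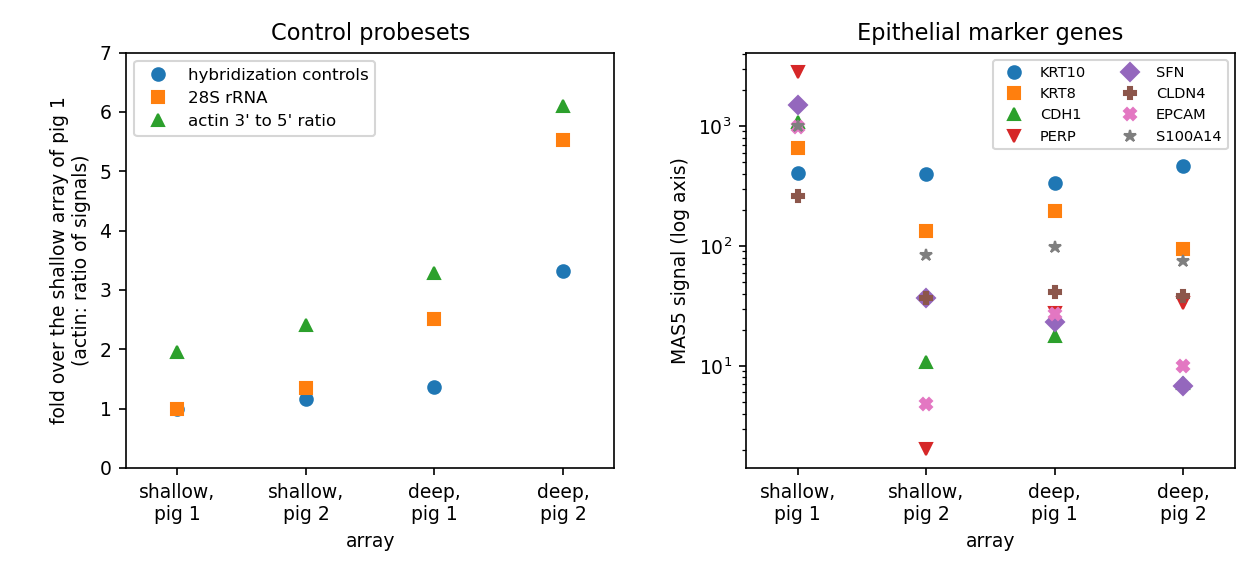
Left, control probesets on each of the 4 arrays (horizontal axis): hybridization controls and 28S rRNA as fold over the shallow array of pig 1, and the actin 3' to 5' signal ratio; points are single arrays, and all 3 measures read highest on the deep array of pig 2. Right, MAS5 signal (log axis) of 8 epithelial marker genes on the same arrays, where CDH1 reads 1084 on the shallow array of pig 1 and at most 17.7 on the others, while KRT10 lies between 338 and 465 on all 4.

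Fibroblasts from deep wounds had less messenger RNA of cell-cycle genes than those from shallow wounds. They had more of genes for collagens and proteoglycans, interferon-induced proteins, growth factor signalling and oxidative and xenobiotic defence. All 24 measured cell-cycle genes were lower on the deep array in each pig, by a mean log2 difference of -1.94. Each of these 6 lists passed camera at a preset correlation between genes (largest adjusted p = 7.1e-06), and none passed with an estimated correlation (smallest adjusted p = 0.449). In single-gene tests with the pig as block, 34 probesets rose and 15 fell among 14399. None was called without the block, without the filter on dim probesets or with the actin ratio as covariate. Among named genes by their brightest probeset, the largest rises were in GSTA1, a glutathione transferase, 24.9-fold higher in deep, and SERPINA6, corticosteroid-binding globulin, 24.3-fold higher. CAVIN2, a caveolar coat protein, was among the genes that fell, and its shallow signal was 1068 in pig 1 and 68.4 in pig 2. Without the shallow array of pig 1 its log2 difference was -1.11, with the highest absent control in place of its signal on the deep array of pig 2.

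Among named genes represented by their brightest probeset, 16 rose in deep cultures. GSTA1 rose from 19.9 ± 6.43 to 513 ± 250, a log2 difference of 4.64 ± 0.35 (SE; limma, adjusted p = 0.00891). SERPINA6 rose from 45.0 ± 19.1 to 1180 ± 776 (4.61 ± 0.31, adjusted p = 0.00777). SCARA5, a ferritin receptor, rose from 437 ± 282 to 4104 ± 2674 (3.23 ± 0.26, adjusted p = 0.00962). AGTR1, the angiotensin II type 1 receptor, rose 7.76-fold, from 18.6 ± 0.811 to 145 ± 28.3 (2.96 ± 0.41, adjusted p = 0.0438). IGFBP2, an insulin-like growth factor binding protein, rose 4.85-fold, from 1056 ± 16.6 to 5151 ± 772. PTN, the heparin-binding growth factor pleiotrophin, rose 6.89-fold, and SERPINF1, pigment epithelium-derived factor, rose 5.76-fold. ACTG2, smooth muscle gamma actin, rose 5.94-fold, from 604 ± 159 to 3591 ± 958. FBXO32, a ubiquitin ligase of muscle atrophy, rose 6.28-fold and GLIPR1 rose 7.81-fold. The interferon-induced ISG12(A) rose 7.33-fold. RSAD2, the antiviral protein viperin, was below the highest control for absent transcripts on both shallow arrays and rose at least 6.73-fold (adjusted p = 0.0438). The remaining 4 were COL8A1, PRELP and ISG15, given with their lists, and PPP1R3B, a glycogen-targeting phosphatase subunit named after its value was seen (log2 difference 1.95). Single arrays set the size of some of these rises. The log2 difference of SERPINA6 was 5.33 without the deep array of pig 1 and 3.88 without that of pig 2, and that of SCARA5 3.95 and 2.51; for RSAD2 the bounds were 2.16 and 3.34. Without the shallow array of pig 1 or pig 2 it was 2.52 or 3.94 for SCARA5 and 1.80 or 3.25 for SERPINF1.

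The genes that fell in deep cultures were 5. CAVIN2 fell from 568 ± 707 to 19.2 ± 18.6, a log2 difference of -4.28 ± 0.47 (limma, adjusted p = 0.0295), and its shallow level rested on the array of pig 1, at 1068 against 68.4 in pig 2. On the deep array of pig 2 it read 5.99, below that array's highest control for absent transcripts at 30.9, so the fall there was at least 2.21-fold and over both pigs at least 8.55-fold. With that control's signal in place of its own, the log2 difference was -1.11 without the shallow array of pig 1, -5.08 without that of pig 2 and -3.13 without the deep array of pig 1. It was -3.06 without the deep array of pig 2. The kinetochore gene CENPF fell from 410 ± 143 to 46.5 ± 52.4 (-3.82 ± 0.55, adjusted p = 0.0453). CENPF too was below the absent controls on the deep array of pig 2, at 9.45, so its fall was at least 10.0-fold in that pig and at least 7.83-fold over both. The log2 difference was -2.25 without that array, and without the deep array of pig 1 it was -3.69 with the control's signal in place. PCLAF, a factor that binds the replication clamp PCNA, fell 6.67-fold, from 2088 ± 1524 to 270 ± 39.1, with a log2 difference of -2.74 that was -1.91 without the shallow array of pig 1 and -3.56 without that of pig 2. RACGAP1, which acts in cytokinesis, fell 3.98-fold, and SERPINB2, plasminogen activator inhibitor 2, fell 3.65-fold, from 6858 ± 3300 to 1825 ± 634. With the crossed pairing CAVIN2 (limma, adjusted p = 0.100) and SERPINB2 (limma, adjusted p = 0.0615) lost the call. Next in order of unadjusted p, and not past the threshold, were TEX30 (log2 difference -1.92, adjusted p = 0.0526), CEP55 (-2.53), ACOT7 (-2.02), DNMT1 (-1.80), CDCA3 (-2.11), SFN (-4.23) and NUP54 (-1.62). CEP55 and SFN were below the absent controls on the deep array of pig 2. Without the shallow array of pig 1 the differences of the other genes lay between -1.43 for ACOT7 and -1.17 for DNMT1, and those of CEP55 and SFN, with the control's signal in place, were -1.47 and -0.47. CEP55 and CDCA3 act in cell division and DNMT1 maintains DNA methylation at replication.

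A further 4 genes were called through a probeset that was not their brightest and are named here after their values were seen: ACTB, RND3, CTSC and NIP7. For the cytoskeletal actin ACTB the called probeset read 237 and 560 on the shallow arrays and 1832 and 13346 on the deep arrays. It rose by 3.76 on the log2 scale, while the brightest ACTB probeset differed by 0.47 (adjusted p = 0.620). The actin 3' to 5' ratio was likewise highest on the deep array of pig 2.

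**Figure D2:**
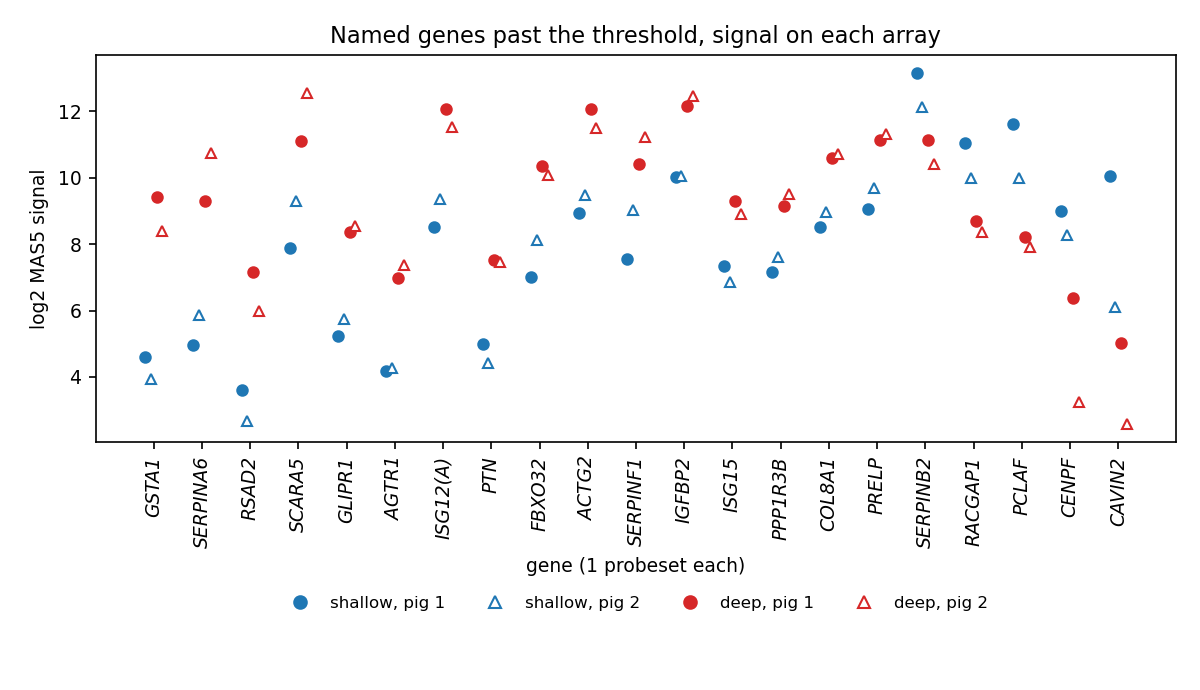
Log2 MAS5 signal (vertical axis) of the 21 named genes past the threshold by their brightest probeset (horizontal axis), with blue for shallow and red for deep, circles for pig 1 and triangles for pig 2; each point is 1 array. In all 21 both deep arrays lie on the same side of both shallow arrays, and the 5 genes at the right fell, from SERPINB2 to CAVIN2.

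The 49 called probesets included 26 with a gene name, for 25 genes, and 23 without, and 9 were below the absent controls on at least 1 array. A larger number, 1995, had an unadjusted p under 0.05 against 720 expected by chance, 999 of them higher and 996 lower in deep. With each array centred on its median, this split was 1206 higher and 788 lower and 5 probesets were called. No probeset was called by limma without the pig as block (smallest adjusted p = 0.0597, 1885 at an unadjusted p under 0.05). None was called without the filter on dim probesets either (smallest adjusted p = 0.0913, 2246 at an unadjusted p under 0.05). Fits without 1 array had no pig block and left 1 array at a depth, so their counts cannot be set against the 49. They are given only as ranges among the processing settings below.

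The pigs shared many large differences. At least 2-fold in both, 315 probesets were higher and 235 lower in deep, and 83 differed by as much in opposite directions. Pairing each shallow array with the deep array of the other pig gave 229 higher, 200 lower and 52 in opposite directions. The difference between pigs at the same depth, pig 2 minus pig 1, gave 43 higher, 57 lower and 114 in opposite directions. Pearson's r between the deep minus shallow differences of the pigs was 0.34 across probesets, and Spearman's rho was 0.32. With the crossed pairing r was 0.41 and rho 0.42, so the correlations do not favour the pairing used. Probesets are not independent replicates. With pig 1 alone 2260 probesets differed at least 2-fold, and with pig 2 alone 1758, counts chosen after the data were seen.

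Genes of the extracellular matrix were higher in deep cultures as groups, with few members past the threshold singly. The collagen list rose by a mean log2 of 0.65 over 19 measured genes (camera, adjusted p = 1.31e-06, but adjusted p = 0.449 with an estimated correlation). Of these, 1 rose over all probesets and 8 rose adjusted over the list alone, and 13 had both deep arrays above both shallow arrays. The short-chain collagen COL8A1 rose from 432 ± 97.3 to 1625 ± 88.1 (1.93 ± 0.27, limma, adjusted p = 0.0438). Differences that did not pass were 1.54 ± 0.27 for COL6A3, 1.27 ± 0.30 for COL5A2, 0.99 ± 0.27 for COL1A2 and 1.01 ± 0.46 for COL3A1, whose named probeset was dim at 23.1 ± 5.16 in shallow.

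The list of proteoglycans, hyaluronan and elastic fibres rose by a mean of 0.94 over 18 genes (camera, adjusted p = 5.09e-07, but adjusted p = 0.449 with an estimated correlation). Over all probesets 1 rose, PRELP, a leucine-rich proteoglycan, from 684 ± 215 to 2406 ± 227, and 12 rose adjusted over the list alone. ASPN, asporin, read 28.5 ± 12.4 in shallow and 752 ± 715 in deep (4.36 ± 0.67, adjusted p = 0.0527), and the difference was 3.18 without the deep array of pig 2 and 5.54 without that of pig 1. DPT, dermatopontin, differed by 2.19 ± 0.40, and DCN, decorin, by 0.79 ± 0.30. The hyaluronan synthase HAS3 went the other way (-1.57 ± 1.02), with 512 on the shallow array of pig 1 and at most 27.8 on the others.

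The adhesive glycoprotein and integrin list rose by a mean of 0.43 over 16 genes (camera, adjusted p = 0.00153, but adjusted p = 0.449 with an estimated correlation), with 0 members past the threshold in either count. Its largest differences were 0.93 ± 0.30 for POSTN, 0.92 ± 0.34 for FN1, 0.84 ± 0.31 for SPARC and 0.72 ± 0.31 for THBS2. The list of matrix proteases and inhibitors rose by a mean of 0.41 over 19 genes (camera, adjusted p = 0.00784, but adjusted p = 0.449 with an estimated correlation). Over the list alone 7 rose and 3 fell, SERPINB2 among the latter. The collagenase MMP1 differed by 1.25 ± 0.37 (adjusted p = 0.192), MMP3 by 2.14 ± 0.63 (1.33 to 2.95 with 1 array left out), TIMP2 by 1.43 ± 0.28 and TIMP1 by 0.89 ± 0.36. Quantile normalization ended both calls (means 0.09 and 0.21, adjusted p = 0.523 and 0.0708). So did leaving out the shallow array of pig 1 (0.29 and 0.31, adjusted p = 0.299 and 0.238). The 99th percentile of signal was 4732 and 5142 on the shallow arrays and 5619 and 6886 on the deep arrays, and with the actin ratio as covariate the means were 0.01 and -0.0030.

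Contractile genes of myofibroblasts rose by a mean of 0.39 over 18 genes (camera, adjusted p = 0.00424, but adjusted p = 0.449 with an estimated correlation), and 2, ACTG2 and CNN1, rose adjusted over the list alone. ACTA2, the smooth muscle actin that marks myofibroblasts, read 9027 ± 2051 in shallow and 15489 ± 2658 in deep (0.79 ± 0.30, limma, adjusted p = 0.302). CALD1 differed by 0.84 ± 0.30, and MYLK by -1.44 ± 0.93, with opposite signs in the pigs and a value below the absent controls on the deep array of pig 2. The list's call was lost under quantile normalization (0.14, adjusted p = 0.438) and without the shallow array of pig 1 (0.24, adjusted p = 0.0786). Markers of smooth muscle and pericytes rose by 0.83 over 8 genes (camera, adjusted p = 0.00218, but adjusted p = 0.449 with an estimated correlation). ACTG2 rose over all probesets, and ACTG2 and CNN1 (1.29 ± 0.34) rose adjusted over the list alone. HIGD1B differed by 0.98 ± 0.52 (0.16 without the deep array of pig 2, 1.81 without that of pig 1) and RGS5 by 0.63 ± 0.55 (-0.74 without the shallow array of pig 1, 1.99 without that of pig 2).

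Genes of TGF-beta and activin signalling showed no shared direction, with a mean of -0.20 over 17 genes (camera, adjusted p = 0.603) and 0 members past the threshold in either count. TGFB1 read 202 and 120 on the shallow arrays and 88.7 and 91.2 on the deep arrays (-0.79 ± 0.36, limma, adjusted p = 0.386). The activin antagonist FST differed by -1.97 ± 1.17, with 3496 on the shallow array of pig 1 and at most 200 on the others, and ID1 by -1.07 ± 0.27. Growth factors and receptors rose by a mean of 0.81 over 21 genes (camera, adjusted p = 7.1e-06, but adjusted p = 0.449 with an estimated correlation). Of these 2 rose over all probesets, IGFBP2 and AGTR1, and 5 adjusted over the list alone. IGFBP5 read 130 ± 32.9 in shallow and 2305 ± 2653 in deep (3.39 ± 0.56, adjusted p = 0.0616). Its deep signal was 429 in pig 1 and 4181 in pig 2, and the difference was 1.75 without the deep array of pig 2 and 5.03 without that of pig 1. IGF1 differed by 1.85 ± 0.51, or 1.11 without the shallow array of pig 1 and 2.58 without that of pig 2.

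**Figure D3:**
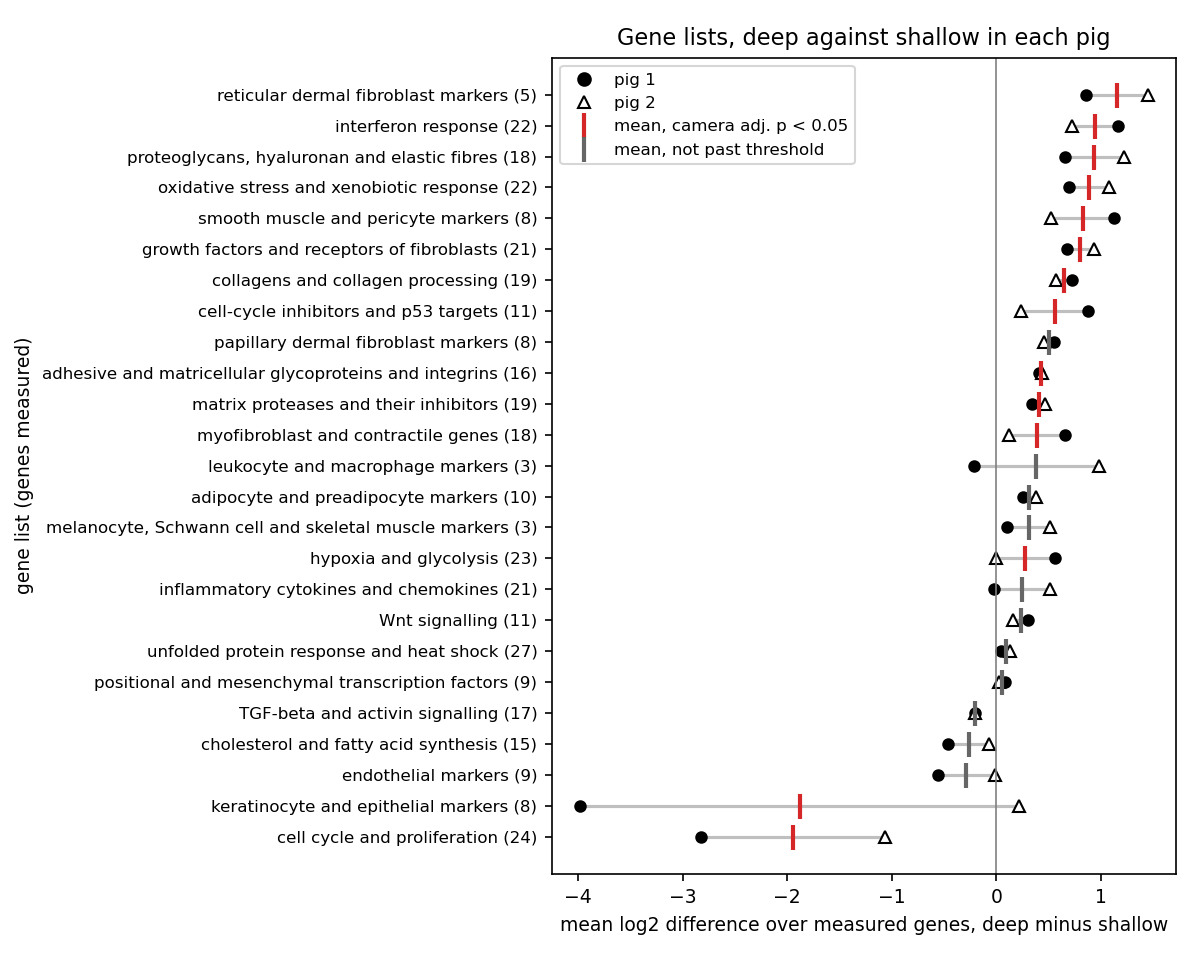
Mean log2 difference, deep minus shallow, over the measured genes of each of the 25 lists (horizontal axis; number of genes in brackets), with circles for pig 1, triangles for pig 2 and a bar for their mean, red where camera's adjusted p passed. The cell-cycle list lies lowest at -1.94 with both pigs below 0, and the epithelial list at -1.88 spans -3.98 in pig 1 and 0.22 in pig 2.

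Interferon-response genes rose by a mean of 0.94 over 22 genes (camera, adjusted p = 3.84e-09, but adjusted p = 0.449 with an estimated correlation). Of these 2 rose over all probesets and 8 adjusted over the list alone, and 15 had both deep arrays above both shallow arrays. RSAD2 is given above. ISG15, a ubiquitin-like modifier, rose from 140 ± 31.7 to 555 ± 110 (2.00 ± 0.29, limma, adjusted p = 0.0453). OAS1 differed by 1.99 ± 0.30 (adjusted p = 0.0524) and MX1 by 1.66 ± 0.34. Inflammatory cytokines and chemokines did not pass as a list (mean 0.24 over 21 genes, camera, adjusted p = 0.0841). Within it 1 gene rose adjusted over the list alone, the adhesion molecule VCAM1 (1.24 ± 0.26), and 1 fell, the chemokine CXCL2 (-1.16 ± 0.29); 0 passed over all probesets.

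Genes of oxidative stress and xenobiotic defence rose by a mean of 0.89 over 22 genes (camera, adjusted p = 1.34e-06, but adjusted p = 0.449 with an estimated correlation). The median was lower, at 0.49, with GSTA1 (4.64) and ALDH1A1 far above it. GSTA1 rose over all probesets and 6 genes rose adjusted over the list alone. ALDH1A1, which makes retinoic acid, read 123 ± 91.5 in shallow and 2075 ± 1469 in deep (4.10 ± 0.64, limma, adjusted p = 0.0558; 3.26 to 4.95 with 1 array left out). The extracellular glutathione peroxidase GPX3 differed by 2.07 ± 0.59, or 0.50 without the shallow array of pig 1 and 3.64 without that of pig 2, and catalase, CAT, by 1.44 ± 0.28. The unfolded protein response and heat shock list did not pass (mean 0.09 over 27 genes, camera, adjusted p = 0.475), with 0 members past the threshold in either count. Its largest differences were 1.19 ± 0.31 for DDIT3 and 1.15 ± 0.28 for HMOX1.

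Cell-cycle genes fell by a mean log2 of 1.94 over 24 genes (camera, adjusted p = 1.15e-19, but adjusted p = 0.536 with an estimated correlation of 0.833 between genes). That estimate rests on 1 residual per gene. The small p at the preset correlation assumes that genes vary almost independently, and it does not measure variation between cultures. On all 24, both deep arrays were below both shallow arrays, and 21 were at least 1.5-fold lower in both pigs. CENPF fell over all probesets and 23 fell adjusted over the list alone. RRM2, a subunit of ribonucleotide reductase, read 1258 ± 1121 in shallow and 146 ± 16.1 in deep (-2.75 ± 0.50, limma, adjusted p = 0.0771), and -1.68 without the shallow array of pig 1. CDC20 differed by -2.51 ± 0.62 (-3.40 to -1.63 with 1 array left out), and the mitotic kinase PLK1 was below the highest control for absent transcripts on both deep arrays and at least 4.35-fold lower there (adjusted p = 0.118). With the control's signal in place its log2 difference was -1.12 without the shallow array of pig 1 and -3.12 without that of pig 2. The mean difference was 7.08-fold in pig 1 and 2.09-fold in pig 2. The shallow array of pig 1, which carried the epithelial transcripts, was also highest in cell-cycle genes, and without it the mean was -1.18. Cell-cycle inhibitors and p53 targets rose by a mean of 0.56 over 11 genes (camera, adjusted p = 8.42e-04, but adjusted p = 0.449 with an estimated correlation). Of these 2 rose adjusted over the list alone, BTG2 (1.60 ± 0.31) and CDKN1A (1.38 ± 0.27), and 0 over all probesets. BTG1 differed by 0.73 ± 0.28 and SESN1 by 0.66 ± 0.37. Without the shallow array of pig 1 this list's mean was 0.33 (adjusted p = 0.0962).

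Hypoxia and glycolysis genes rose by a mean of 0.28 over 23 genes (camera, adjusted p = 0.0263, but adjusted p = 0.561 with an estimated correlation), with 0 members past the threshold in either count. ENO2 differed by 0.93 ± 0.46, GAPDH by 0.83 ± 0.32, HIF1A by 0.68 ± 0.31 and PFKP by -0.73 ± 0.28. The call was lost under quantile normalization (0.18, adjusted p = 0.166) and without the shallow array of pig 1 (0.23, adjusted p = 0.238), the shallow array of pig 2 (0.33, adjusted p = 0.161) or the deep array of pig 1 (0.05, adjusted p = 0.476). Cholesterol and fatty acid synthesis did not pass (mean -0.26 over 15 genes, camera, adjusted p = 0.152), with 0 members past the threshold in either count. HMGCS1, an early enzyme of the pathway, differed by -1.11 ± 0.34. SQSTM1, which the fixed list held though it is not a gene of this synthesis, differed by 1.25 ± 0.31. That is the largest difference in the list and runs against its mean.

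Positional and mesenchymal transcription factors had a mean of 0.06 over 9 genes (camera, adjusted p = 0.757). Adjusted over the list alone, PRRX1 rose (1.39 ± 0.26) and TCF21 fell (-0.93 ± 0.27), with 0 past the threshold over all probesets. Wnt signalling did not pass (mean 0.23 over 11 genes, camera, adjusted p = 0.290), with 0.97 ± 0.29 for DKK3 and -0.76 ± 0.29 for DKK2, neither past the threshold in either count. Markers of reticular dermal fibroblasts, those of the deeper dermis, rose by a mean of 1.15 over 5 genes (camera, adjusted p = 0.00153, but adjusted p = 0.449 with an estimated correlation). Adjusted over the list alone 4 rose, DPT, THY1 (1.98 ± 0.44, or 1.29 without the shallow array of pig 2 and 2.68 without that of pig 1), CNN1 and ACTA2, and 0 over all probesets. The remaining member, MFAP5, differed by -0.50 ± 0.34 and was lower in deep in both pigs. DPT and MFAP5 are also in the proteoglycan list and CNN1 and ACTA2 in the contractile list. Of the measured members THY1 alone is in no other list, so this list is not separate evidence. The ACTA2 difference of 0.79 was 0.042 with quantile normalization and 0.25 with the actin ratio as covariate. Papillary markers, those of the upper dermis, did not pass (mean 0.50 over 8 genes, camera, adjusted p = 0.0759). Of these CTSC (1.28 ± 0.28) and PTGDS (1.26 ± 0.39) rose adjusted over the list alone. The difference between the reticular and papillary lists was not tested.

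Among markers of other cell types, keratinocyte and epithelial genes had a mean of -1.88 over 8 genes (camera, adjusted p = 0.00105, but adjusted p = 0.576 with an estimated correlation), with 0 past the threshold over all probesets and 3, SFN, CDH1 and KRT8, adjusted over the list alone. The difference came from the shallow array of pig 1, where SFN read 1486, S100A14 1002 and EPCAM 979. Without that array the mean was 0.55 (adjusted p = 0.565). Endothelial markers had a mean of -0.29 over 9 genes (camera, adjusted p = 0.497), with -1.78 ± 0.43 for CLDN5, which fell adjusted over the list alone, and -1.09 ± 0.42 for ICAM2, both below the absent controls on the deep array of pig 2. With the control's signal in place the ICAM2 difference was 0.046 without the shallow array of pig 1. Leukocyte markers had a mean of 0.38 over 3 genes (adjusted p = 0.369), with 0.43 ± 0.58 for CD86 (-0.76 to 1.63 with 1 array left out) and 0.39 ± 0.36 for CORO1A. Adipocyte markers had a mean of 0.32 over 10 genes (adjusted p = 0.113), with 1.26 ± 0.40 for CEBPA and 0.79 ± 0.26 for PNPLA2. Melanocyte, Schwann cell and muscle markers had a mean of 0.31 over 3 genes (adjusted p = 0.510), with 0.61 ± 0.60 for MITF (-0.077 to 1.30 with 1 array left out) and 0.28 ± 0.41 for EDNRB. None of the members of these last 3 lists passed in either count.

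In total 14 of the 25 lists passed with camera at the preset correlation, 12 higher and 2 lower in deep. With an estimated correlation 0 passed, and with fry 1 did, the adhesive glycoproteins (adjusted p = 0.0372). The estimated correlation decides little here, as the fit leaves 1 residual degree of freedom. Across all 14399 probesets, both deep arrays lay above both shallow arrays in 23.2% and below in 25.5%, against 16.7% each way by chance.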

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

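All tests in this part were chosen after the results were seen, apart from the gene lists they run on and the fits by depth with and without the pig as block.

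Control probesets, which no comparison used, read differently at the 2 depths, with both deep arrays above both shallow arrays in each measure. The deep mean was 3.41 times the shallow mean for 28S ribosomal RNA and 2.17 times for hybridization controls. It was 2.15 times for the actin 3' to 5' ratio and 1.19 times for the GAPDH 3' to 5' ratio. With 2 arrays a depth, part of any difference between depths could come from array quality, and with the actin ratio as covariate limma called 0 probesets and 283 had an unadjusted p under 0.05. With this covariate the log2 difference was -0.34 for CAVIN2, -0.26 for CENPF, 0.15 for RND3 and 1.22 for SCARA5, all nearer 0 than without it, while it was 5.96 for GSTA1 and 2.96 for ACTG2. Because the covariate is correlated with depth, both a share of array quality in the former genes and a loss of precision stay open.

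The first pattern weighed was the set of group differences between depths, lower cell-cycle genes and higher matrix, growth factor, oxidative stress and interferon genes. A first step runs from the shallow array of pig 2 to the deep array of pig 1, and a second between the 2 deep arrays. The 28S, hybridization and 3' to 5' measures differ more in the second step, so differences caused by them alone should be larger there. The share of probesets above the highest absent control went the other way. It was 73.4% on the shallow array of pig 2, and 64.7% and 61.6% on the deep arrays of pig 1 and pig 2. The steps therefore cannot test a cause that follows this share. The excess of the deep-to-deep step in the direction of the pattern was -1.529 (SE 0.22) on the log2 scale for 24 cell-cycle genes. It was -0.4233 (SE 0.12) for 37 collagen and proteoglycan genes and -1.382 (SE 0.31) for 22 interferon genes. Means of these sets with the actin covariate were -1.657 (SE 0.17), 0.5328 (SE 0.11) and 1.251 (SE 0.26). On these arrays the values argue against the 28S, hybridization and 3' to 5' measures as the whole cause in these 3 sets. A quality cause that follows the share above the absent controls stays open in them. The SEs are over genes on single arrays and do not measure variation between cultures. For 21 growth factor and 22 oxidative stress genes the excess was -0.2989 (SE 0.27) and -0.6481 (SE 0.34) and decided nothing. With the covariate the means were 0.4503 (SE 0.22) and 0.7189 (SE 0.30), too close to 0 against an SE over genes to decide on the actin trend. Other quality measures stay open. For 16 adhesive glycoprotein genes and 19 proteases and inhibitors the excess was 0.1674 (SE 0.15) and 0.1785 (SE 0.16) and the covariate left means of 0.01034 and -0.003026, so quality could be the whole cause there, and in every set a partial share, wound depth, culture conditions and other differences between single cultures stay open.

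The second pattern was the higher cell-cycle level in shallow cultures, for which the epithelial transcripts on the shallow array of pig 1 were weighed as a cause. In pig 2, whose shallow array lacked them, the mean difference of the 24 genes was -1.066 (SE over genes 0.19), with 24 of 24 lower in deep. This is 1 pair of cultures, and that SE does not measure variation between cultures. In that pair the value argues against epithelial cells as the whole cause. They may still add to the larger difference in pig 1, -2.82.

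The third pattern was the epithelial transcripts themselves, seen in 6 of the 8 measured markers, for which the design gives no biological explanation by depth, since the shallow array of pig 2 lacked them. Because several of these passed the filter on dim probesets only through that array, the test used the other 8 of the 16 markers on the array, which had failed the filter, with signals below the absent controls raised to them. Of these 3, DSP at 950, KRT18 at 243 and S100A9 at 209, were at least 4-fold above the highest other array, against 14 of 1485 other named genes that failed it (Fisher's exact test, two-sided, p = 6.64e-05) and 0 of 116 genes of other lists (p = 0.0001806), which argues against poor quality of that array as the whole cause. Collagen and proteoglycan genes lay a median log2 of only -0.2409 from the shallow array of pig 2, which argues against a sample of another cell type in place of fibroblasts. A candidate explanation is an admixture of epithelial cells in that culture, and the labels name no sort that would remove them; KRT10 was level on all arrays and KRT8 only 3.37-fold higher.

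The 4 arrays can be split into 2 and 2 in 3 ways, too few to give a share under 0.05. The split by depth, with the pig as block, called 49 probesets. Each other split was also fitted with a block, either of the remaining splits in turn, and the larger count was 0, so 1 of the 3 reached the real count. Without a block the split by depth called 0 as well.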

How the results depend on the processing

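The actin covariate and the 2-fold counts without a pig or an array were added after the data were seen, and the rest was planned. In every setting 38 to 49 of the 49 called probesets were tested, and all tested kept their direction except 1 with the actin covariate. Dropping or crossing the block, or changing the filter or variance prior, leaves the log2 difference itself unchanged. Direction could not turn in those settings. The number called moved with nearly every choice. It was 0 with no replicate block, 202 (119 higher, 83 lower; 45 shared with the 49) with the crossed replicate block, 96 (66, 30) with quantile normalization, 5 (5, 0) with median centring, 0 with no dim filter, 217 (132, 85) with a stricter filter, 97 (69, 28) with an offset, 3 (2, 1) with no variance trend, 109 (78, 31) with a robust prior and 0 with the actin covariate. Leaving out 1 array gave 0 to 1597 (0 to 735 higher, 0 to 862 lower), with the lone array assumed to vary like the other depth. Probesets at an unadjusted p under 0.05 were 727 to 3366 without 1 array and 283 with the actin covariate. Probesets at least 2-fold in both pigs were 1818 with no dim filter, 290 with a stricter one; with 1 pig left out, those at least 2-fold in pig 1 or pig 2 alone were 2260 and 1758. Without 1 array no count in both pigs exists; instead, 470 had both deep arrays at least 2-fold from the shallow array of pig 2 and 507 the deep array of pig 1 from both shallow arrays, where the shared array raises agreement by an unmeasured amount. The correlation of the pigs' differences was 0.41 with crossed pairs, 0.12 with no dim filter and 0.41 with a stricter one. Lists past camera were 9 to 14 without 1 array, 0 with an estimated correlation and 1 with fry. Without the block the same 14 lists passed as with it, with list means that cannot differ in this balanced design, and the calls of all 21 named genes were lost. The stricter filter left no genes of the melanocyte list, so it gave no value.

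Signs reversed in 38 values, and the cause was not tested. With the actin covariate these were list means of proteases (-0.0030), Wnt (-0.0093), positional factors (-0.12), epithelial (0.52), adipocyte (-0.14) and melanocyte markers (-0.067), and HAS3 (0.27), FN1 (-0.19), SPARC (-0.12), MYLK (1.48), IGFBP5 (-0.24), GAPDH (-0.26), CDH1 (0.44), EPCAM (2.14), ICAM2 (0.87), HIGD1B (-0.93), RGS5 (-0.56), PNPLA2 (-0.15) and MITF (-0.58). Leaving out 1 array or 1 pig gave these ranges: cholesterol synthesis -0.61 to 0.079, hypoxia -0.00016 to 0.56, positional factors -0.025 to 0.14, epithelial markers -4.31 to 0.55, HAS3 -4.21 to 1.06, MYLK -3.73 to 0.85, FST -5.15 to 1.22, CDH1 -6.59 to 0.075, EPCAM -5.89 to 1.79, S100A14 -3.55 to 0.035, CD86 -0.96 to 1.83, RGS5 -0.74 to 1.99, MITF -0.44 to 1.67 and EDNRB -0.33 to 0.89. List means also had opposite signs in the pigs for inflammatory genes (-0.023 in pig 1, 0.51 in pig 2) and leukocyte markers (-0.22 and 0.98). The epithelial and positional lists, HAS3, FST, CDH1, EPCAM, S100A14 and RGS5 turned when the shallow array of pig 1 was left out. Positional factors (-0.11) and endothelial markers (0.26) turned with no dim filter, the latter (0.11) with a stricter one, and the unfolded protein response (-0.00094) with quantile normalization. Of the other values of single genes and lists, 1610 showed no change of call, 130 gained and 193 lost the call. Signal over background limits RSAD2, PLK1 and CDH1, which lay below the absent controls on both arrays of 1 depth, and CAVIN2 and CENPF, which did so on 1 deep array. EPCAM and HAS3 lay below the highest absent control on both arrays of pig 2. Their values without the shallow array of pig 1 are therefore differences near background.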

Other observations

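The values of single arrays and the actin covariate in this part were chosen after the results were seen, and the fits without an array were planned.

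Beyond the epithelial markers, other genes read high on the shallow array of pig 1 alone. They include UPK1B, a uroplakin of epithelial surfaces, at 328 against at most 39.1 on the other arrays, and the membrane protein genes MAL, at 339 against at most 31.4, and TM4SF1, at 1382 against at most 49.3. The hyaluronan synthase HAS3 (18.4-fold over the highest other array), the activin antagonist FST (17.5-fold) and CAVIN2 (15.6-fold) belong to the same set. The fall of CAVIN2 in deep cultures therefore rests in large part on this array. Without it, and with the highest absent control of the deep array of pig 2 in place of the signal there, the log2 difference was -1.11.

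Genes of cholesterol and fatty acid synthesis set the 2 deep arrays apart. Their median log2 difference was -0.94 from the shallow array of pig 2 to the deep array of pig 1, and 0.92 from the deep array of pig 1 to that of pig 2. At the preset correlation the list passed camera without the deep array of pig 2 (mean -0.61, adjusted p = 2.06e-04), without the shallow array of pig 1 (-0.42, adjusted p = 0.00148) and with the actin ratio as covariate (-1.09, adjusted p = 1.35e-11), and not with all arrays. With an estimated correlation and all arrays adjusted p was 0.561, and the estimated correlation was not tried in these other settings.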
